A study of Homo sapiens with 4 samples.

How the data were processed

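The 4 libraries come from SZ95, an immortalized human sebaceous gland line grown, per the labels' protocols, in a medium with 10% serum and 5 ng/ml epidermal growth factor. Per the same protocols, libraries were made from 500 ng of total RNA with a Lexogen QuantSeq kit, which primes from the poly(A) tail and reads the 3' end of each transcript. The groups are normoxia and 8, 24 and 48 h at 1% oxygen and 5% carbon dioxide, with 1 library each. The design text also gives a count of 4 for the cells incubated, and whether a library pools several cultures is not given in the sources used here. The submitters' processing notes name the hg19 genome build, Bowtie2 and edgeR, without versions. The gene annotation, the counting program and whether it used strand are not given in the sources used here.

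Each library was deposited as a table of 25737 rows that pair a gene symbol with a log2 expression value. The values were deposited on a log2 scale, and their make-up, which the labels do not state, was inferred here from the low values. In every library the values fit the log2 of a normalized count plus 1, where the normalized count is a library-size-equalized pseudo-count of whole reads with 1 common dispersion, fitted here as 0.134. With this model, whole reads were recovered for 100% of the values of the 7863 genes under 50 reads, within 0.002 log2 units. A read was worth 0.9948, 1.0238, 1.1303 and 0.8684 normalized counts at 0, 8, 24 and 48 h. On data simulated with this same model, 100% of reads were recovered exactly in the 7260 rows under 50 reads. That check tests neither the model itself nor the recovery of larger counts. The normalized totals were 7170806, 7264363, 8854771 and 9058384, so the scaling was not by library total alone. As the deposited values are log2 and not counts, the branch of the design for other units was used. The recovered reads are inferred and were used only for depth and for counting intervals, a step added after the values were seen.

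Log2 ratios to normoxia are differences of the deposited values. Folds are 2 to the power of these differences and so carry the pseudocount of 1, which understates the change of genes with few reads. Intervals at 95% come from the exact Clopper-Pearson limits of a gene's share of its reads in the 2 libraries compared, and reads without molecular identifiers are not independent molecules. Where a library had 0 reads for a gene no fold is printed.

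Of 24462 symbols, 286 had more than 1 row. The row with the highest mean was kept, a choice made after the tables were seen, and 1275 rows were dropped. Reads were found in at least 1 library for 18530 symbols. The floor was the median of their mean log2 value, 5.94, or 60.2 normalized counts, and 9265 genes lay above it. A gene counted as higher or lower at a ratio of 2-fold or more. Simulated counting noise alone, without differences between cultures, gave at most 1 gene past 2-fold in a comparison, in each of 100 simulations. A further simulation, again with counting noise alone, changed 200 genes among 9265. Of those changed by 3-fold, between 99 and 100% were past 2-fold in the comparisons of 8, 24 and 48 h, with 99.5% at 24 h. Of those changed by 1.5-fold, between 1 and 1.5% were past it. These shares do not cover differences between cultures.

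The design, the alternatives and the gene lists were fixed before the data were examined. The named genes were, for each time, the 10 highest and 10 lowest log2 ratios among genes above a naming floor, the 66.7 percentile of mean levels at 7.49 log2 units or 178.3 normalized counts, leaving out symbols of uncharacterized loci and small RNAs. From each gene list, up to 4 members above the floor with the largest ratio at any time were named, and all members of the lists of HIF targets, cytokines and lipid droplet proteins. ADM, VEGFA and CA9 were named as label checks. Genes named outside this rule are said to be so. Some results were left out because they are withheld for evaluation. The family of splicing factor genes was defined after low members had been seen, and the pseudogene HNRNPA1P10 was left out of it after its values were seen.

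Of 51 gene lists, 45 had at least 5 genes above the floor, a minimum chosen once the list sizes were known. A list's median was placed among the medians of 10000 random lists of the same size, matched on mean expression in 10 bins. It is said to stand apart below the 2.5 or above the 97.5 percentile, which describes these libraries and is not a test across cultures. Over the 3 times, 48 of 135 placements stood apart, 14 at 8 h, 18 at 24 h and 16 at 48 h. Lists of genes drawn at random would give about 5%. The gene lists hold related genes and share members, and all times use 1 normoxia library. The 5% is therefore no gauge of chance for them. In a simulation of the 24 h comparison with lists of 25 genes drawn at random, 8 of 100 unshifted lists and 94 of 100 lists shifted by 0.6 lay outside the limits.

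Overlaps between genes were taken from GENCODE release 29, which is on another build than the one the notes name. It was used for gene names, strand, exon overlap and the GC content of the last 500 bases, and no coordinate is given. Of the 9265 genes, 9170 were found in it by symbol or synonym, 2560 with an exon that overlaps a gene on the opposite strand and 448 with a same-strand overlap alone. Leaving out the genes with an opposite-strand overlap or not found gave 6610 genes. Reads of 2 genes that overlap cannot be told apart where counting ignores strand, and near-identical copies such as HSPA1A and HSPA1B, or SMN1 and its copy, are uncertain for the same reason.

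The alternatives were centring each library on the median level of 24 reference genes, centring on the median gene, quantile normalization, a pseudocount of 5, no floor, a higher floor (8.19 log2 units, 4633 genes), rules of 1.5-fold and 3-fold, the mean for the median, unmatched random lists and lists without shared genes. Scaling to equal library totals, centring on the median log2 ratio of the reference genes and leaving out overlapping genes were added after the data were seen. Centring on the reference genes' median level moved all log2 ratios by -0.194 at 8 h, -0.091 at 24 h and -0.268 at 48 h. The median of levels differs from the median of ratios, and centring on the latter moved them by -0.070, -0.085 and 0.053, while equal totals moved them by -0.019, -0.303 and -0.336. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.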

Results

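SZ95 cells, an immortalized line derived from human sebaceous gland, were kept in normoxia or placed in a chamber at 1% oxygen and 5% carbon dioxide for 8, 24 or 48 h. Messenger RNA was measured by sequencing near the 3' ends of transcripts, with 1 library per time and 4 in all. There are no replicates, so no difference below has a replicate check, no p-value is given, and genes are named by a fixed rule of size. All times are compared with 1 normoxia library, and none has a normoxia library of its own. Effects of hypoxia therefore cannot be told apart from those of time in culture. The libraries held 7207446 reads in normoxia, 7095622 at 8 h, 7833930 at 24 h and 10430627 at 48 h, as recovered from the deposited values. At least 1 read was found for 16265, 15759, 15990 and 16718 genes in that order, and 9265 genes lay above the floor set on mean level. The fibronectin gene FN1 took the largest share of the normalized total in each library, with 1.92% in normoxia, 2.54% at 8 h, 6.11% at 24 h and 11.12% at 48 h. Ranges given after a fold are 95% intervals that cover counting error only.

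The hypoxia-responsive genes ADM, VEGFA and CA9 were higher in all 3 hypoxia libraries than in normoxia. ADM, which encodes the vasodilator peptide adrenomedullin, had 240 normalized counts in normoxia and was higher by 11.3-fold at 8 h (9.97 to 13), 22.6-fold at 24 h (19.9 to 25.9) and 20.1-fold at 48 h (17.7 to 23.1). VEGFA, the main angiogenic growth factor, was higher by 2.55-fold (2.32 to 2.83), 4.93-fold (4.51 to 5.42) and 4.82-fold (4.42 to 5.29). CA9, a carbonic anhydrase of the cell surface, was higher by 3.49-fold (3.03 to 4.05) and 7.01-fold (6.14 to 8.08), and then by 2.03-fold at 48 h (1.75 to 2.38). These 3 genes were chosen beforehand as a check of the labels, and each went with the label of its library. CA9 overlaps a gene on the opposite strand, so part of its reads may belong to that gene.

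The list of HIF target genes, those under the oxygen-sensitive transcription factor HIF, had 37 members above the floor. Of these, 20 were higher by 2-fold or more at 8 h, 28 at 24 h and 24 at 48 h, and 0 were lower by that much at any time. The list's median log2 ratio to normoxia was 1.19 at 8 h, 1.92 at 24 h and 1.20 at 48 h. The middle 95% of random lists matched on expression ran from -0.05 to 0.13, from -0.10 to 0.37 and from -0.15 to 0.34. The glucose transporter gene SLC2A3 was the highest of them at 24 and 48 h, with 9.04-fold at 8 h (8.04 to 10.2), 31.3-fold at 24 h (27.9 to 35.3) and 38.1-fold at 48 h (34.1 to 43). EGLN3, which encodes a prolyl hydroxylase that marks HIF for breakdown, was higher by 9.22-fold, 22.5-fold and 22.8-fold, from 24 reads in normoxia. NDRG1 was higher by 5.76-fold, 17.2-fold and 11.7-fold. Members that peaked before 48 h included PFKFB4, an enzyme that sets the pace of glycolysis, at 4.20-fold, 3-fold and 1.46-fold, and BNIP3, a mitophagy receptor, at 2.2-fold, 5.72-fold and 3.55-fold. PDK1, a kinase that restrains pyruvate dehydrogenase, was 1.37-fold higher at 8 h, and 1.38-fold and 1.27-fold lower at 24 and 48 h.

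**Figure D1:**
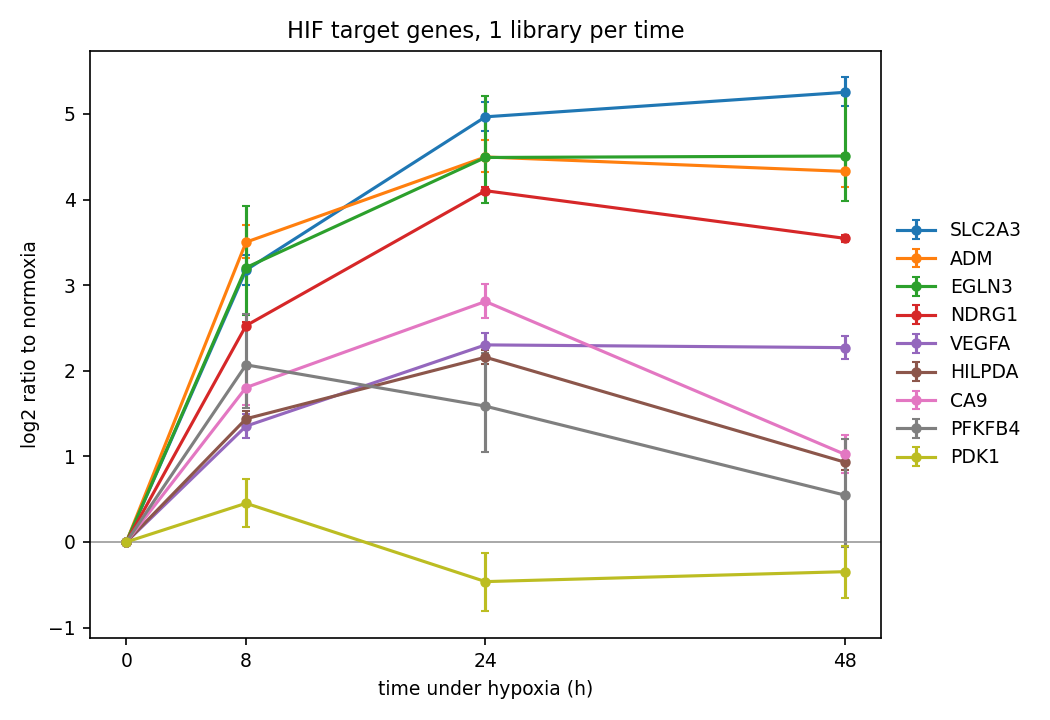
Log2 ratio to normoxia (y axis) against time under hypoxia in hours (x axis) for 9 HIF target genes, 1 library per time; bars are 95% counting intervals. SLC2A3, ADM, EGLN3 and NDRG1 stay above 3 at 24 and 48 h, while CA9, HILPDA and PFKFB4 are lower at 48 h than at 24 h, and PDK1 lies near 0.

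The first comparison sets 8 h of hypoxia against normoxia. Among genes above the naming floor of 178.3 normalized counts, to which the rankings of highest and lowest genes here are limited, the largest increases were in ADM, the CREB coactivator gene CRTC2, EGLN3, SLC2A3, ANGPTL4, ARRDC3, NDRG1, ATXN2L, SIK1 and C10orf10, from 11.3-fold for ADM to 5.04-fold for C10orf10. ANGPTL4, an inhibitor of lipoprotein lipase, was 8.04-fold higher at 8 h, 5.44-fold at 24 h and 1.82-fold at 48 h. CRTC2 was 9.35-fold higher at 8 h (7 to 13.3), from 45 reads in normoxia. ANGPTL4, ARRDC3 and C10orf10 overlap a gene on the opposite strand. In all, 119 of 9265 genes were higher by 2-fold or more and 321 were lower. Centring each library on the median level of reference genes gave 79 higher and 411 lower, and centring on their median log2 ratio, added after the data were seen, gave 103 and 348.

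Most of the large decreases at 8 h were in genes that share sequence with a gene on the other strand. Above the naming floor, the 10 lowest genes were CAPN12, MIF-AS1, FAM166A, TAPT1-AS1, BEST1, WDR38, ATP6V1C2, ANKRD19P, RUSC1-AS1 and DDTL, and 8 of these 10 have an annotated overlap on the opposite strand. CAPN12 had 14633 normalized counts in normoxia, 1.07 at 8 h, 13115 at 24 h and 12756 at 48 h. ACTN4, the actinin gene it overlaps, named after its values were seen, had 15781, 16326, 14203 and 13920. MIF-AS1 had 5954 normalized counts in normoxia, a recovered count of 0 reads at 8 h, 11488 at 24 h and 7754 at 48 h, beside 5950, 5216, 11488 and 7749 for MIF. Without genes that have such an overlap, 86 of 6610 were higher and 88 were lower at 8 h. The decreases of overlapping genes at 8 h are therefore not read as expression here, and among them are DDIT3, PES1, NOP16, DGAT1, SYVN1 and BCL2L1.

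**Figure D2:**
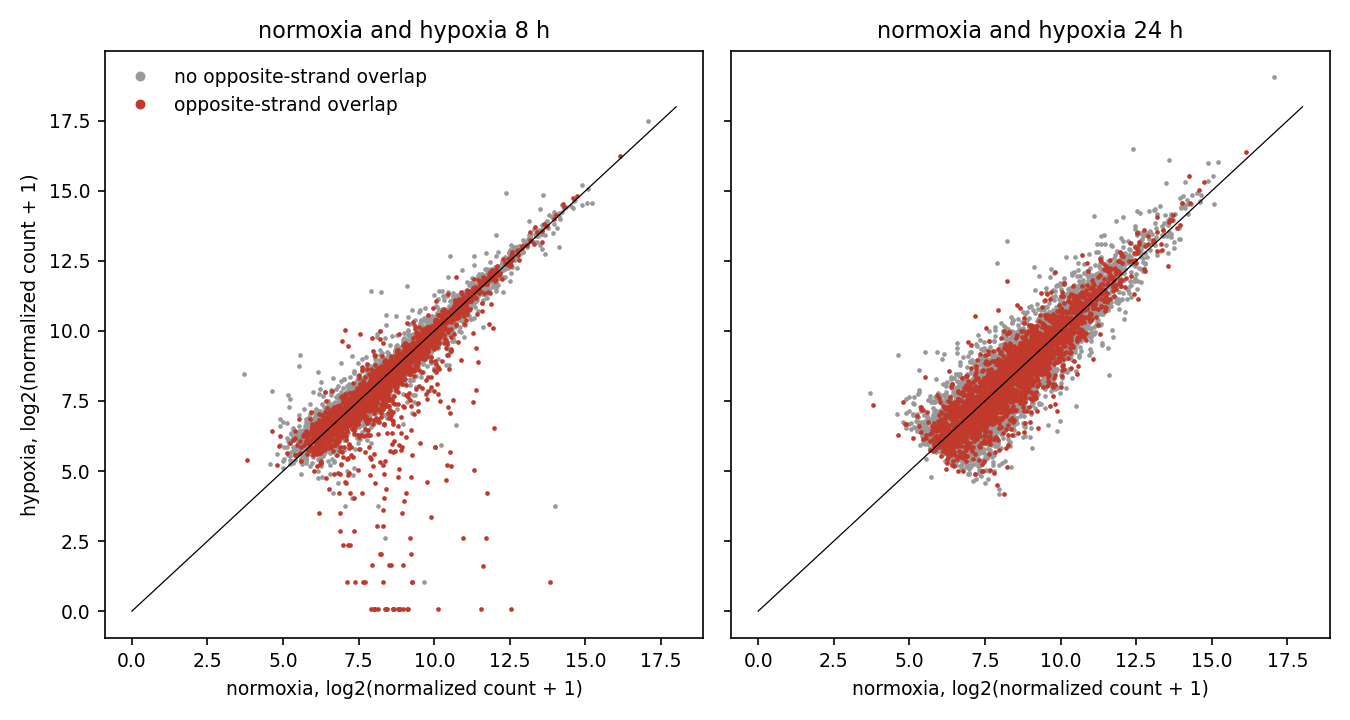
Level in normoxia (x axis) against level at 8 h (left) and 24 h (right) of hypoxia (y axis), both as log2 of the normalized count plus 1; each point is 1 of the genes above the floor that were found in the annotation, in red where an exon overlaps a gene on the opposite strand. At 8 h, 104 of the 2560 overlapping genes lie 4-fold or more below their lowest level in the other libraries, against 10 of the 6162 genes with no overlap.

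Among genes above the naming floor without an overlap, a ranking made after the values were seen, the lowest at 8 h were TAPT1-AS1, ANKRD19P, YIF1B, PRICKLE3, DIMT1, BAX, CTNS, TFRC, R3HDM4 and CTSZ. TFRC, the transferrin receptor gene, was the 1 gene of these 10 that was also lower by 2-fold or more at 24 and 48 h. It was lower by 3.93-fold at 8 h (3.41 to 4.57), 10.7-fold at 24 h (8.61 to 13.9) and 4.82-fold at 48 h (4.17 to 5.61). The rest, BAX among them, were low at 8 h alone, as the overlapping genes were, and since overlaps were looked up in another annotation than the one used for counting, their decreases are not read as expression either. The growth factor and feedback genes of the EGF pathway were low as a group, with a median of -0.60 at 8 h against -0.15 to 0.17 in random lists. Of its 16 members above the floor, 6 were lower by 2-fold or more and 0 were higher, among them HBEGF, an EGF receptor ligand, at 3.18-fold, the transcription factor gene ETV5 at 2.56-fold and the ERK phosphatase gene DUSP6 at 2.34-fold. Heat shock protein genes had a median of 0.46 at 8 h, with all 15 above 0 and 0 past 2-fold.

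At 24 h of hypoxia, HIF targets and the keratin gene KRT17 were higher, and TFRC, PSAT1 and genes of ribosome biogenesis were lower. Beside the HIF targets SLC2A3, ADM, EGLN3, NDRG1, BHLHE40 and ANKRD37, the largest increases above the naming floor were in CRTC2 at 13.4-fold, ATXN2L at 9.03-fold, SIK1 at 8.27-fold and KRT17 at 8-fold (7.65 to 8.37). The largest decreases above that floor were in TFRC and then SMOC1 at 9.13-fold (7.47 to 11.5), the splicing factor gene SFPQ at 8.99-fold (8.02 to 10.2) and PSAT1, an enzyme of serine synthesis, at 8.97-fold (7.60 to 10.8). FGFBP1 was lower by 7.66-fold, LRP8 by 6.79-fold, MAT2A by 6.67-fold, PPIL1 by 6.61-fold, CTPS1 by 6.02-fold and RRP15 by 5.66-fold. BHLHE40, ANKRD37, MAT2A and PPIL1 overlap a gene on the opposite strand. In all, 696 genes were higher by 2-fold or more and 753 were lower, and 549 and 561 of the 6610 genes without an overlap. Scaled to equal library totals, an alternative added after the data were seen, the split was 364 higher and 1409 lower.

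Ribosome biogenesis was the lowest of the gene groups at 24 h. Of its 21 members above the floor, 16 were lower by 2-fold or more and 0 were higher, with a median of -1.68 against -0.30 to 0.39 in random lists. RRS1, needed for assembly of the large ribosomal subunit, was lower by 13.8-fold at 24 h (8.76 to 26.7) and 6.90-fold at 48 h (5.03 to 10). NOLC1 was lower by 4.67-fold at 24 h, and at 48 h by 2.72-fold. At 48 h, 14 of the 21 were lower, with a median of -1.25 against -0.33 to 0.38. The list already stood apart at 8 h, with a median of -0.49 against -0.13 to 0.16, also without overlapping genes. At that time 4 of the 21 were lower by 2-fold or more and 0 lay above normoxia. PES1 and NOP16, among these 4, overlap a gene on the opposite strand. The genes of the ribosomal proteins themselves had a median of 0.49 at 24 h with 0 of 51 past 2-fold in either direction, and this list no longer stood apart after quantile normalization or without overlapping genes. Genes of the mitochondrial ribosome and of mitochondrial biogenesis had medians of -0.12, -0.69 and -0.82 at the 3 times, with 7 of 23 lower by 2-fold or more at 24 h and 6 at 48 h, among them MRPL15 at 2.5-fold and 2.85-fold. The value at 8 h left the range of random lists in the main setting but not with quantile normalization, with the mean or with unmatched random lists.

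The list of the ATF4 and amino acid response was low as a group at 8 and 24 h, with medians of -0.39 and -0.75. Random ranges were -0.09 to 0.13 and -0.19 to 0.36. The list holds genes of amino acid supply, other genes under the transcription factor ATF4, and ATF4 itself. ATF4 had log2 ratios of 0.28 at 24 h and 0.92 at 48 h. At 8 h, 4 of the 29 were lower by 2-fold or more, of which DDIT3 and SLC7A11 overlap a gene on the opposite strand, and the 21 members without an overlap had a median of -0.34. At 24 h, 9 of the 29 were lower by 2-fold or more and 1 was higher, ATF3, with a log2 ratio of 1.43. PSAT1 and SLC7A11, the cystine transporter gene, which was lower by 15.3-fold at 24 h and overlaps a gene on the opposite strand, were the lowest of them. At 48 h the median was -0.19, inside the random range. PSAT1 was then lower by 3.12-fold (2.83 to 3.46) and the glutathione-degrading enzyme gene CHAC1 by 1.67-fold, after 4.39-fold at 8 h. The EGF pathway list stayed low, at -0.49 and -0.47, with ETV5 lower by 9.30-fold at 24 h and 5.81-fold at 48 h. By 2-fold or more, 7 of its 16 members were lower and 2 higher at 24 h, and 7 were lower and 1 higher at 48 h. EGFR, which overlaps a gene on the opposite strand, was higher by 4.89-fold and 5.37-fold. IER3 was the other higher member at 24 h, with a log2 ratio of 1.34. The list no longer stood apart at 24 and 48 h with the higher floor on expression, nor at 8 h when the mean replaced the median.

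At 48 h, the median of genes that run mitosis was lower than in normoxia, and those of matrix and basal adhesion genes were higher. By 2-fold or more, 21 of 36 genes of mitosis were lower, and 9 of 22 matrix and 6 of 20 basal adhesion genes were higher. Above the naming floor, SLC2A3, EGLN3, ADM, BHLHE40, NDRG1, YPEL2, KRT17, SIK1, CRTC2 and GAB2 had the largest increases. KRT17 was higher by 9.73-fold (9.31 to 10.2), YPEL2 by 10.2-fold and the signalling adaptor gene GAB2 by 7.39-fold. SMOC1 and SFPQ were the lowest above that floor, by 8.56-fold (7.18 to 10.4) and 8.11-fold (7.34 to 9). They were followed by GABRP, a subunit of a GABA receptor, at 7.48-fold, FGFBP1 at 7.34-fold, the cyclin gene CCNB1 at 6.85-fold (5.78 to 8.24), the chemokine gene CXCL1 at 6.58-fold (5.89 to 7.39), MPZL2, C1orf74, which overlaps a gene on the opposite strand, C1orf116 and the mitotic kinase gene AURKA at 4.88-fold (4.42 to 5.42). In all, 794 genes were higher and 783 lower by 2-fold or more, and 622 and 567 without overlapping genes. The split was 394 higher and 1585 lower with equal library totals, 457 and 1404 with centring on the median level of reference genes, and 883 and 691 with centring on their median log2 ratio, so its direction at 48 h depends on the scaling.

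Genes of mitosis were close to normoxia at 8 h and became progressively lower. The list's median was -0.03 at 8 h, -0.72 at 24 h and -1.05 at 48 h, with 0, 5 and 21 of its 36 members lower by 2-fold or more and 0 higher at any time. CCNB1 was lower by 1.29-fold, 3.65-fold and 6.85-fold, and AURKA by 1.20-fold, 3.12-fold and 4.88-fold. Genes of DNA replication, in contrast, had medians of -0.01, 0.16 and 0.08, all inside the range of random lists, and E2F1 and the licensing factor gene CDT1 were higher at 48 h by 2.37-fold and 3.39-fold. The cell cycle inhibitor gene CDKN1C was higher by 6.31-fold at 24 h and 8.01-fold at 48 h. Its list of cell cycle inhibitors and p53 targets lay inside the random range at each time.

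Lists of matrix, adhesion and epithelial-mesenchymal genes had medians above the random range at 24 and 48 h. Genes of collagen modification and extracellular matrix had medians of 0.32, 0.97 and 0.88 at the 3 times, with 2, 11 and 9 of 22 members higher by 2-fold or more and 0 lower. FN1 was higher by 1.34-fold, 3.93-fold and 7.32-fold, and P4HA1, a collagen prolyl hydroxylase, by 1.69-fold, 4.83-fold and 3.83-fold. COL1A1 stood alone in being 12.1-fold higher at 8 h (9.15 to 17.1), with 1.08-fold lower and 1.20-fold higher values at the later times. It is 1 of the 2 members counted as higher at 8 h. Its increase was in that library alone, where COL1A2 had a log2 ratio of 0.36. How the 8 h library was counted is not known, so a counting effect is not excluded for it. Epithelial-mesenchymal genes had a median of 0.55 at 24 h and 1.43 at 48 h, when 10 of 14 were higher by 2-fold or more, among them CYR61 at 4.30-fold and ITGA5, an integrin subunit, at 3.52-fold. At 24 h, 3 of the 14 were higher and 1 was lower by 2-fold or more, and VIM, which encodes vimentin and overlaps a gene on the opposite strand, had a log2 ratio of -0.97 at 24 h and 2.15 at 48 h. The fibroblast markers COL1A2, COL3A1, FBN1 and THY1, named after their values were seen, were also higher at 48 h, from 51.7, 43.8, 17.9 and 8.9 normalized counts in normoxia to 364.8, 217.3, 96.3 and 54.6, and all but COL1A2 lay below the floor. Of the 12 fibroblast markers listed, others did not rise, among them FAP, from 15.9 to 14.7, and DCN, at 0.0 in both. Without genes that another list also holds, the epithelial-mesenchymal value at 24 h lay inside the random range. Basal keratin and adhesion genes had medians of 0.20, 0.95 and 0.76, with KRT17 and the integrin gene ITGB4, at 3.92-fold and 3.35-fold, among the 8 and 6 of 20 that were higher by 2-fold or more at 24 and 48 h. At 8 h that list no longer stood apart when the floor was removed or the mean replaced the median.

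Glycolysis genes were higher at each time, with medians of 0.38, 0.92 and 0.49, and 3, 9 and 5 of 20 members higher by 2-fold or more. At 8 h 1 member, GAPDH, named after its values were seen, was lower by that much, with a log2 ratio of -1.15. Its decrease was at 8 h alone, and a counting effect is not excluded for it. HK2, which makes glucose 6-phosphate, was higher by 3.52-fold, 3.79-fold and 1.73-fold, and ENO2 by 1.54-fold, 4.12-fold and 3.04-fold. At 48 h the list lay inside the random range with quantile normalization. Angiogenic factors had medians of 0.23, 0.79 and 0.85, with the endothelin gene EDN1 higher by 6.13-fold at 48 h. They no longer stood apart at 8 h without genes that another list also holds, nor at 48 h without a floor. HIF pathway components had 0.26, 0.65 and 0.72, but stood apart at no time with the higher floor or without shared genes. Histone demethylases and related oxygenases had 0.41, 0.58 and 0.48, led by KDM3A at 5.16-fold and KDM6B at 4.65-fold at 24 h, and with the higher floor they stood apart at 8 h alone. Without shared genes they no longer stood apart at 48 h. Mitophagy and autophagy genes had medians of 0.56 at 24 h and 0.89 at 48 h, with ULK1, the kinase that starts autophagy, higher by 2.79-fold and 3.30-fold.

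**Figure D3:**
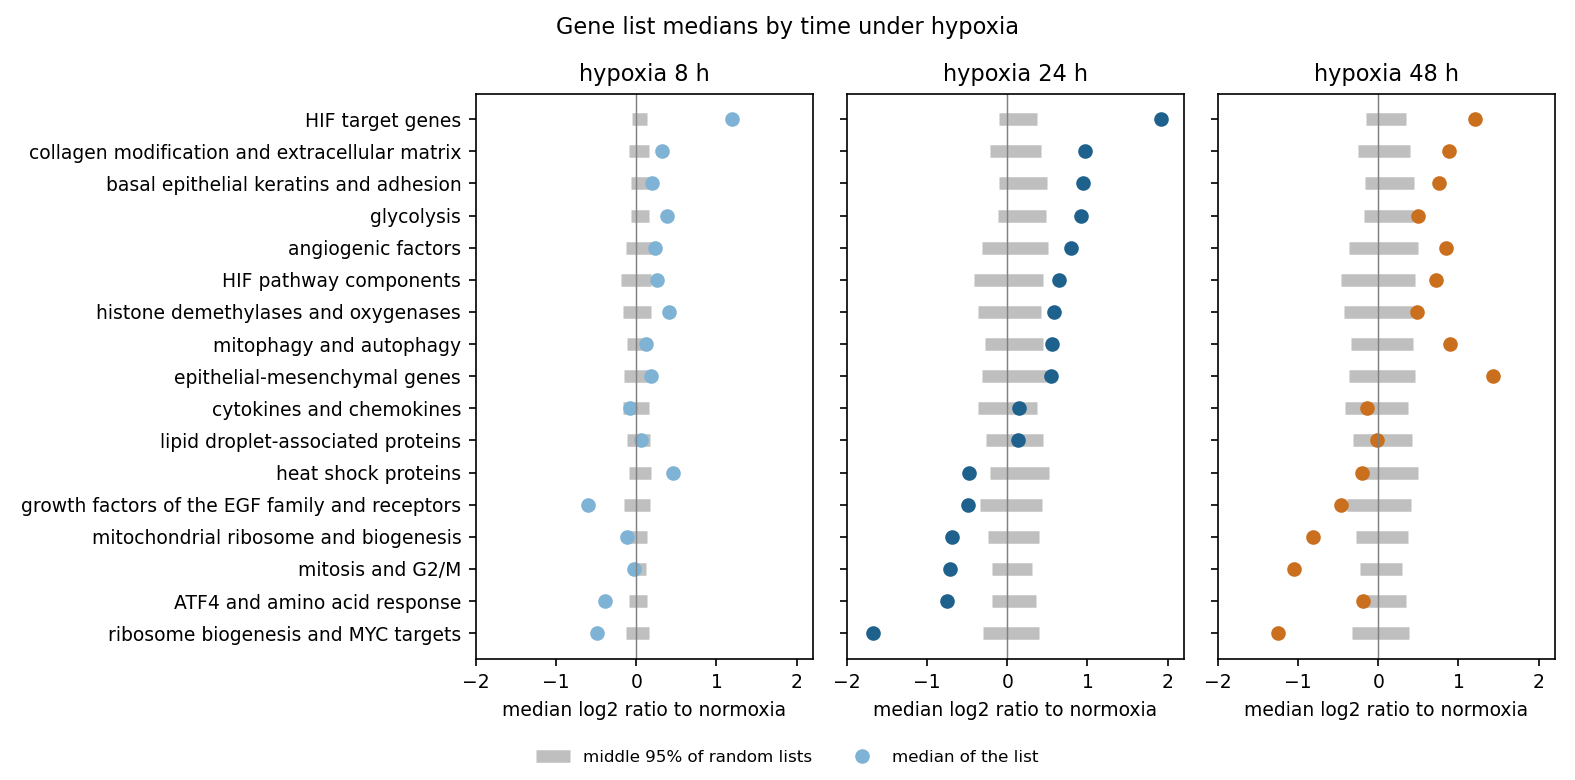
Median log2 ratio to normoxia (x axis) of 17 gene lists (y axis) at 8, 24 and 48 h of hypoxia; grey bars are the middle 95% of 10000 random lists matched on expression. HIF target genes lie highest at 8 and 24 h, ribosome biogenesis lies lowest at 24 and 48 h, and cytokines and lipid droplet genes lie within the bars.

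Cytokine genes, one subject of the series title, moved in both directions and did not shift as a group. Of 47 cytokine and chemokine genes in the list, 19 lay above the floor. At 8 h 1 was higher and 1 lower by 2-fold or more, at 24 h 4 and 2, and at 48 h 6 and 5. Their medians of -0.08, 0.15 and -0.14 lay inside the range of random lists. IL1B, which encodes interleukin-1 beta, was lower at each time, by 2.90-fold at 8 h (2.41 to 3.55), 5.77-fold at 24 h (4.50 to 7.71) and 10.4-fold at 48 h (7.78 to 14.5). The neutrophil-attracting chemokine genes CXCL1, CXCL6 and CXCL8 were lower at 48 h, by 6.58-fold, 2.78-fold and 2.27-fold (1.94 to 2.65), as was CXCL11 by 2.93-fold (2.01 to 4.47). CXCL8 was 1.01-fold lower at 24 h, with a range of 0.884 to 1.15 that includes no difference. TGFB2 was higher by 2.62-fold at 24 h (2.31 to 2.97) and 6.92-fold at 48 h (6.22 to 7.76), IL15 by 5.48-fold and 7.16-fold, CXCL10 by 3.22-fold and 2.83-fold, and IL11 and IL32 by 2.51-fold and 2.02-fold at 48 h. IL6 was higher by 3.46-fold (2.24 to 5.86), 3.18-fold and 3.47-fold, from 24 reads in normoxia, and overlaps a gene on the opposite strand. Genes of NF-kB signalling and of the interferon response did not stand apart at any time. RELB, an NF-kB subunit, was 3.06-fold lower at 8 h and 3.02-fold and 3.68-fold higher at 24 and 48 h. Its decrease was at 8 h alone, and a counting effect is not excluded for it. Cytokine and Toll-like receptor genes had a median of 0.41 at 24 h, led by IL1RAP and IL6R at 2.63-fold and 2.60-fold. That list no longer stood apart with the higher floor or with the mean.

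Genes of lipid droplet proteins, the other subject of the title, likewise held 2 genes that went opposite ways. HILPDA, a hypoxia-inducible droplet protein that inhibits triglyceride breakdown, was higher by 2.71-fold at 8 h (2.55 to 2.88), 4.46-fold at 24 h (4.21 to 4.74) and 1.91-fold at 48 h (1.79 to 2.03). PLIN2, the perilipin that coats droplets in most cells, was 1.27-fold higher at 8 h (1.08 to 1.5) and then lower, by 3.28-fold at 24 h (2.54 to 4.38) and 6.10-fold at 48 h (4.54 to 8.55). These were the 2 members that passed 2-fold at any time, of 18 above the floor, out of 32 in the list. Members below the floor were not counted, and 2 of them are named after their values were seen. The lipase gene LIPE had 61.7, 23.6, 17.1 and 16.3 normalized counts at 0, 8, 24 and 48 h. PLIN4 had 95.5, 0.0, 126.5 and 142.7, and a decrease at 8 h alone is not read as expression here. PLIN3 was within 1.13-fold of normoxia at each time. G0S2, an inhibitor of the lipase encoded by PNPLA2, was higher by 1.62-fold at 24 h, and PNPLA2 itself by 1.54-fold. The list's medians were 0.06, 0.13 and -0.01, all inside the random range.

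**Figure D4:**
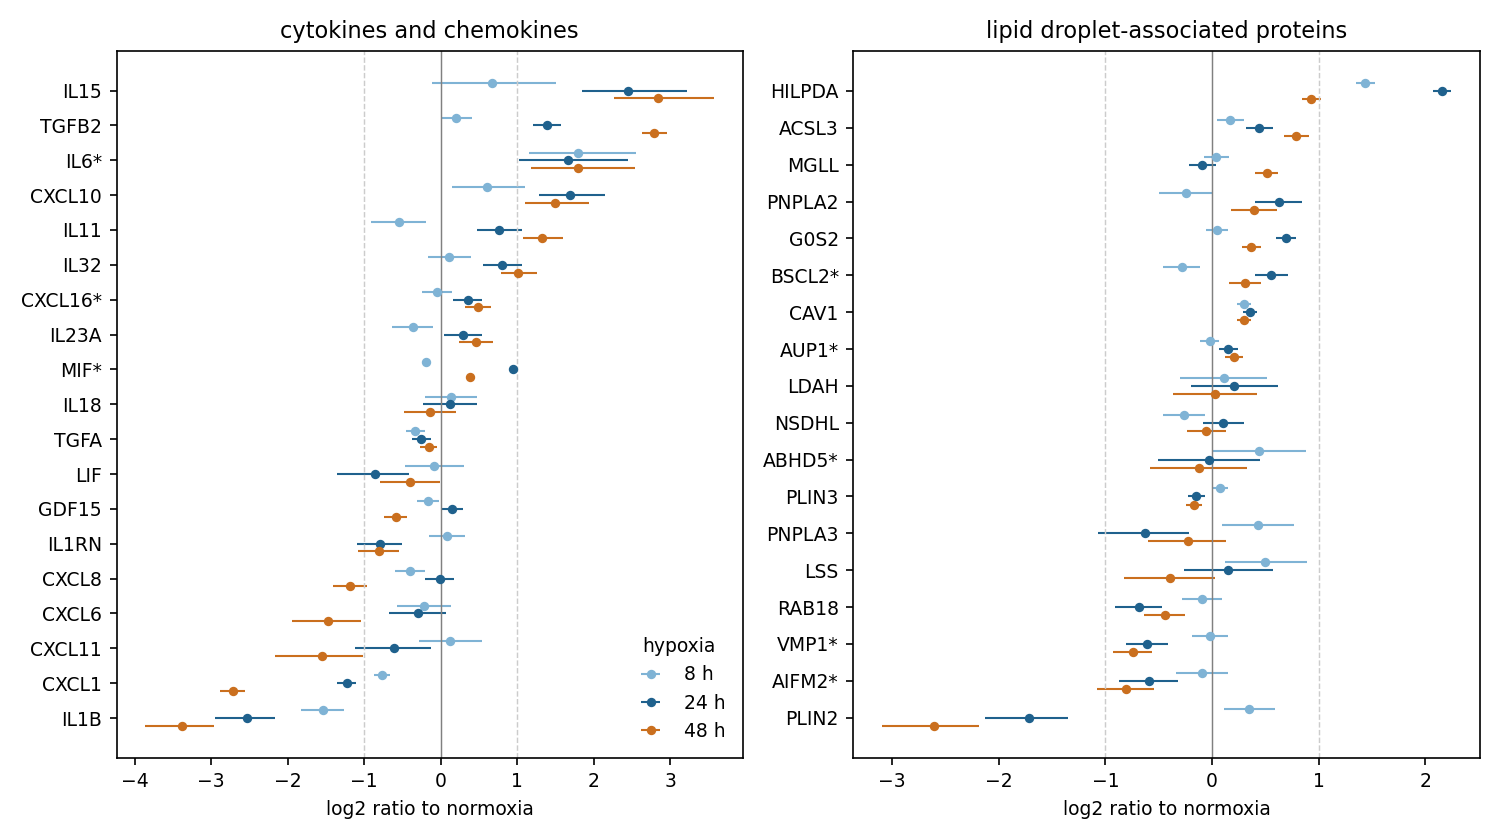
Log2 ratio to normoxia (x axis) of each cytokine gene (left) and lipid droplet gene (right) above the floor at 8, 24 and 48 h of hypoxia; bars are 95% counting intervals, dashed lines mark 2-fold, and * marks an overlap with a gene on the opposite strand. IL1B and PLIN2 lie lowest at 48 h, at -3.37 and -2.61, and HILPDA lies highest among droplet genes at 24 h, at 2.16.

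Other lipid genes did not shift as groups in most cases. Lists of triglyceride synthesis, fatty acid synthesis, fatty acid uptake, sterol efflux and sebocyte markers stayed inside the random range at each time. Within them ELOVL6, a fatty acid elongase, was lower by 2.79-fold at 24 h and 5.37-fold at 48 h, and the acyltransferase gene DGAT2 by 2.28-fold and 3.61-fold. The desaturase gene SCD5 was higher by 2.83-fold and 2.98-fold. Fatty acid oxidation genes had a median of -0.47 at 48 h, below the random range of -0.35 to 0.37, with ACADM lower by 2.25-fold. Genes of androgen, steroid and retinoid metabolism had -0.75 at 48 h, with the retinoic acid-binding protein gene CRABP2 lower by 2.76-fold. That list no longer stood apart without a floor, with the higher floor or with the mean. Cholesterol synthesis at -0.08 and lipolysis at 0.32 stood apart at 8 h alone, and neither did so without overlapping genes.

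From 8 to 24 h, 1263 genes differed by 2-fold or more, 702 higher and 561 lower at the later time, and without overlapping genes 813 did so, 385 higher and 428 lower. From 24 to 48 h, 144 genes did so, 77 higher and 67 lower. COL1A2, a gene named after its values were seen, was 1.93-fold lower than normoxia at 24 h and 6.94-fold higher at 48 h. Across genes, the change from 0 to 8 h and the change from 24 to 48 h had a Pearson correlation of -0.060 and a Spearman correlation of -0.090, and genes are not independent replicates. Without overlapping genes these correlations were -0.124 and -0.108.

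Most genes past 2-fold at 24 h were past it at 48 h too. In numbers, 541 were higher at both times, against 59.6 for independent lists and 0.01 in simulations of counting noise alone. These simulations hold no difference between cultures, so their low counts and covariances are no gauge of chance. Their correlations come from counting noise in the shared normoxia library, so they are no gauge of likeness either. An observed correlation below a simulated one does not show that the times are unlike. Another 500 were lower at both times, against 63.6 and 0. The log2 ratios correlated at 0.89, with 0.50 in simulations of unchanged libraries against the same normoxia library, and their covariance was 0.521 beside a simulated 0.009. For 8 and 24 h, 94 genes were higher at both times, against 8.94 for independent lists, and 40 were lower, against 26.1, with a correlation of 0.24 beside a simulated 0.48 and a covariance of 0.145 beside 0.009. Without overlapping genes, 71 were higher at both 8 and 24 h, against 7.14, and 20 were lower, against 7.47. Their correlation was 0.45 and their covariance 0.154, and no simulation was run on this set alone. Both comparisons use the same normoxia library, which cannot be split, so part of the excess may come from it.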

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

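All tests of the pattern at 8 h were chosen after the pattern had been seen. The flags here rest on differences between single libraries that were not tested, since a time has 1 library.

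Heat shock protein genes had opposite signs at 2 times. Their median log2 ratio to normoxia was 0.456 at 8 h and -0.483 at 24 h, and both lay outside the random range. HSPA1A was higher by 1.88-fold at 8 h and lower by 2.66-fold at 24 h, and its near-identical copy HSPA1B went the same way. HSPE1 was higher by 1.37-fold and then lower by 2.88-fold, and it overlaps a gene on the opposite strand.

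Between 8 and 24 h, 14 genes were 2-fold or more higher at one time and lower at the other. Between 8 and 48 h there were 21, and between 24 and 48 h there were 0. In the set without opposite-strand overlaps the counts were 7 and 9 for the first pair and the second. Those above the naming floor, named after their values were seen, are RELB, the connective tissue growth factor gene CTGF, GAPDH, PACS1, SNHG1, TICAM1 and ZBTB18, all lower at 8 h. Their overlaps were looked up in another annotation than the one used for counting, so a counting effect at 8 h is not excluded for them. GAPDH, an enzyme of glycolysis, had log2 ratios of -1.15 at 8 h, 1.20 at 24 h and 0.57 at 48 h.

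The first pattern weighed is the set of genes near 0 at 8 h that have many reads in the other 3 libraries. Among 9265 genes, 120 lay 4-fold or more below the lowest of the other libraries at 8 h, and 86.7% of these have an exon that overlaps a gene on the opposite strand. That share of genes is 25 times as high among overlapping genes as among genes with no overlap, which fits a library of 8 h counted by strand beside 3 counted without. Dropping of reads from any overlap is argued against by same-strand overlaps, of which 0.0% were lost, and loss of independent antisense transcripts by a median distance of 0.26 log2 units in normoxia between a lost gene and its partner, below the lowest of 1000 shuffled pairings at 1.02. A difference in counting may therefore account for these genes, and how the 8 h library was counted is not given in the sources used here.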

How the results depend on the processing

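No paired analysis was possible because each group has 1 library and no test was run. No list that stood apart and no named gene past its counting interval reversed under any alternative. Of 5022 values of named genes, 4050 stayed within their counting interval and 972 moved beyond it. The 4 scalings that shift a library by 1 value cannot move a list among random lists, so they are no check of the placements. Of 1059 values of lists under the other alternatives, 981 kept their side of the limits, 49 no longer stood apart and 29 newly did. Of 48 placements that stood apart, all were kept with a pseudocount of 5, 42 with quantile normalization, 40 without a floor, 37 with the upper-quarter floor, 39 with the mean, 45 with unmatched lists and 44 without overlapping genes, while 39 of 47 were kept without shared genes. HIF targets kept theirs in each of these.

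Counts of genes depend on the size rule and the floor by construction. With 1.5-fold the counts higher and lower were 417 and 658 at 8 h, 1808 and 1763 at 24 h, and 1846 and 1849 at 48 h. With 3-fold they were 39 and 189, 215 and 231, and 236 and 202. Without a floor they were 1463 and 1563, 2319 and 2375, and 2366 and 2279, and with the upper-quarter floor 63 and 118, 381 and 214, and 434 and 235. Genes that differed from 8 to 24 h numbered 3197, 412, 4876 and 490 in these settings, and from 24 to 48 h 878, 17, 2880 and 47. Centring on the median level of reference genes, which shifts all ratios down, gave 79 higher at 8 h, and 457 higher and 1404 lower at 48 h, where centring on their median log2 ratio, added later, gave 883 and 691. Equal library totals, added after the data were seen, gave 364 and 1409 at 24 h and 394 and 1585 at 48 h, since they too shift all ratios down. Without overlapping genes, also added later, 88 were lower at 8 h and 813 differed from 8 to 24 h, because fewer genes enter and those lost at 8 h are left out. Cytokines at 8 h newly stood apart with the upper-quarter floor, at -0.176 over 8 genes, and the cause was not tested. The correlation across genes of early and late changes went from -0.060 to -0.034 without a floor and -0.124 without overlapping genes.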

Other observations

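Beyond the lists of the report, matrix metalloproteinases and their inhibitors had a median log2 ratio of 0.66 at 48 h, above the random range of -0.44 to 0.47, with PLAUR, the urokinase receptor gene, higher by 2.53-fold and SERPINB2 lower by 7.19-fold. That list lay inside the range with quantile normalization, with the mean, without a floor and without shared genes. Genes of the unfolded protein response had -0.18 at 24 h, at the edge of the random range, and lay inside it in 6 of the alternatives. Lists of the TCA cycle, oxidative phosphorylation, oxidative stress, DNA repair, apoptosis and iron handling did not stand apart at any time. The same held for translation factors, replication-dependent histones, acid-base transport, keratinocyte differentiation and the reference genes. At 48 h oxidative phosphorylation, the TCA cycle and oxidative stress lay close to the lower limit, at the 2.53, 2.74 and 2.93 percentiles. Their medians were -0.12, -0.30 and -0.24. Of the 12 replication-dependent histone genes listed, 5 lay above the floor, so the placement says little about the rest. Of the alarmin genes, 3 lay above the floor, and S100A9 was lower by 2.75-fold, 3.20-fold and 7.89-fold and LCN2 by 1.15-fold, 1.53-fold and 2.87-fold.

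Markers of other cell types, with those singled out here named after their values were seen, were mostly near 0. Of 12 immune cell markers 1 lay above the floor, CD68, of 8 melanocyte markers 1, MITF, of 10 adipocyte markers 2, LPL and PPARG, and of 8 endothelial markers 0. CDH5, an endothelial cadherin gene below the floor, had 88.6, 79.8, 16.1 and 6.7 normalized counts at 0, 8, 24 and 48 h. Of 12 fibroblast markers 2 lay above the floor. COL1A2 had 51.7, 66.6, 26.3 and 364.8 normalized counts, and COL3A1, below the floor, had 43.8, 21.5, 19.5 and 217.3, and FBN1, THY1, PDGFRB and POSTN, all below the floor, went from 17.9, 8.9, 18.9 and 2.0 in normoxia to 96.3, 54.6, 42.1 and 7.2 at 48 h. The markers DCN and LUM had 0.0 and 1.8 at 48 h. FAP, PDGFRA and COL6A3 had 15.9, 0.0 and 1.0 in normoxia and 14.7, 0.9 and 4.3 at 48 h. COL1A1 had 45.8, 565.9, 42.1 and 55.3.

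Of the tests of the next 2 patterns, the one on scaling was chosen after its result was seen, in place of an earlier one whose scalings could not have brought the median near 0, and the splicing family was changed after its values were seen. Genes of ribosome biogenesis were lower at 24 and 48 h, and by less at 8 h, where the median was -0.49 against -0.13 to 0.16. The GC content of the 3' end does not account for this as a whole, since the median at 24 h was -1.79 as residuals from a trend on GC, against -0.34 to 0.37 in random lists. Scaling by 1 factor moves random lists alike, so it cannot set the list apart from them. The list's difference of -1.38 from their lower limit restates that placement and is no separate test. Overlapping genes on the opposite strand do not account for it as a whole, since the 16 members without one had a median of -1.80. A lower expression of these genes under hypoxia remains a hypothesis, as 1 library per time leaves differences between cultures and time in culture open.

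Splicing factor genes of the SR and hnRNP families were looked at because SFPQ, HNRNPM and SRSF2 were low. Over 31 SRSF and HNRNP genes above the floor the median log2 ratio at 24 h was -0.30, against -0.06 to 0.41 in random lists, and -0.28 without HNRNPM and SRSF2. The pseudogene HNRNPA1P10 was left out once its values had been seen, and with it the 32 genes had a median of -0.29. As residuals from the GC trend it was -0.28, so GC content does not account for it as a whole. Named after their values were seen, HNRNPM and SRSF2 were lower by 4.51-fold and 4.21-fold at 24 h, while SRSF4 was higher, with a log2 ratio of 1.20. In all, 8 of the 31 were lower by 2-fold or more and 1 was higher, against 8.13% and 7.51% of all genes. Those lower included SRSF1, SRSF3, SRSF6 and SRSF7, with log2 ratios of -1.67, -1.47, -1.01 and -1.21. HNRNPD and HNRNPAB had -1.36 and -1.16. The shift was thus uneven within the family, and the SR and hnRNP genes were not tested apart.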
